A study of Homo with 6 samples.

How the data were processed

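RNA was sequenced from 6 libraries of MCF-7 cells, 3 grown in normoxia CM and 3 in hypoxia CM for 48 h. Per the labels' protocols, the medium was centrifuged and filtered to remove debris before use, and RNA was extracted with Trizol. Per the submitters' processing notes, the reads were processed with HISAT2 2.0.4, Bowtie2 2.2.5 and RSEM 1.2.8 and the genome build GRCh38.p12. The role of each tool, the annotation, the strand of the libraries and any selection of poly(A) RNA or removal of ribosomal RNA are not given in the sources used here. Without strand, reads of overlapping and antisense genes cannot be told apart.

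The authors deposited 1 table of 15680 genes with estimated read counts (expected counts, not normalized), FPKM and TPM per library. The deposited expected counts are mostly whole, with 1124 to 1204 fractional values per library, and were rounded to whole numbers before the count tests. FPKM values, per the file headers, are scaled by the authors to transcript length and to sequencing depth. TPM values deposited by the authors are scaled to length and have the same sum in each library, so a rise of a few abundant genes lowers all others. The authors' group means in the same table were not used. Of the gene IDs, 15655 matched the reference table by ID. The list of mitochondrially encoded genes had 0 members to test, and these genes were not analysed here.

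Groups and replicate numbers came from the labels. Genes were filtered with filterByExpr, normalised by TMM and tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test, with group as the one factor and Benjamini-Hochberg adjustment at 0.05. CPM values use TMM-scaled library sizes. A table of 38 gene lists was fixed before the data were examined, as were the tests and the rule for named genes. The 34 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over lists, and with an estimated correlation and fry beside it. The counts of members come from the gene test over all genes, with the counts adjusted over the list alone beside them. Named genes were the 8 highest and 8 lowest fold changes past the threshold, with groups that did not overlap and a mean of at least 1 CPM, up to 3 members per list with the smallest p, and 18 genes chosen in advance. Names starting with LOC or LINC, antisense genes and sex-chromosome dosage genes were left out of the first part of the rule. The rule gave 126 names, of which 118 passed the threshold.

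The total count per library was 14982191, 15145965 and 15147465 in normoxia CM and 15143640, 15004166 and 14766987 in hypoxia CM. No pair of libraries agreed within sampling noise. The lowest chi-square per degree of freedom within a group was 1.82 (hypoxia CM replicates 1 and 2) and the highest 6.33. The labels give no batch. In tests on simulated data for this comparison, with 12308 genes and 50 changed genes per size, edgeR recovered 36% of genes changed by 0.25, 80% by 0.5, 94% by 1 and 100% by 2 (log2), with 18 calls among 12078 unchanged genes. Genes that changed by 0.25 were therefore often missed in the simulation, and small changes may be missed in the data. The simulation changed 200 genes of these sizes and a further list of 30, whereas 4156 of 12364 tested genes passed in the data. The adjusted threshold is stricter where fewer genes change, so these recoveries need not hold for the data.

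The alternatives were RLE and upper quartile normalization, no filter, a mean of at least 1 CPM, each library left out, the replicate number as a block, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) and log2(FPKM + 1) of genes with a mean of at least 1, and a 2-fold minimum. A fold change on the log2(value + 1) scale understates that of low genes. Added after the data were seen were a correction for trends of each library with abundance and effective length (loess, span 0.5), counts without the MTRNR2L genes, and U2AF1 with U2AF1L5 counted together. The closing section gives their effect.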

Results

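Messenger RNA levels were measured by RNA sequencing in 6 libraries of MCF-7 cells, an established oestrogen receptor-positive human breast cancer cell line. Conditioned medium (CM) is medium in which other cells have grown and which carries what those cells released and lacks what they consumed. Here it came from MCF-7 cells kept under normal oxygen (normoxia) or low oxygen (hypoxia), and fresh MCF-7 cells were grown in it for 48 h. The normoxia CM and hypoxia CM groups held 3 libraries each. The deposited read counts summed to between 14766987 and 15147465 per library, so a floor of 3 counts lay at 0.198 to 0.203 CPM, the counts per 1000000 counts of a library. Floors of this kind cover counting error only, since reads copied by PCR are not independent molecules. The labels do not say whether the 3 libraries of a group came from separate cultures, and the p-values then measure only the spread between these libraries, which may be technical. The first principal component held 59.5% of the variance and separated the groups, and the second held 14.0%. Coordinates are not printed, because the genome annotation used here for names was of another patch release than the one in the labels.

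The design asks how medium from hypoxic cells changes the transcripts of the cells that receive it, compared with medium from normoxic cells. The oxygen level at which the receiving cells were kept is not in the labels. Of 28 genes of the amino acid response driven by the transcription factor ATF4, 19 fell in hypoxia CM, 1 rose and 8 did not pass, and the list passed camera with the preset correlation and not with an estimated one (adjusted p = 0.088). CHAC1, a member, fell from 17.1 ± 2.30 to 0.641 ± 0.585 CPM (mean ± SD, n = 3 per group). Genes of DNA replication, glycolysis and the heat shock response rose by smaller amounts, in 27 of 36, 18 of 24 and 13 of 15 tested members, with list medians of 0.24, 0.25 and 0.27 (log2). With an estimated correlation DNA replication passed the set test (adjusted p = 0.040), and glycolysis and heat shock did not (adjusted p = 0.10 each). Lower members were found in the lists of YAP and TAZ targets (10 of 15), TGF-beta response (11 of 17), p53 targets (12 of 27) and histones (7 of 10). These 4 lists passed camera with the preset correlation and not with an estimated one (adjusted p = 0.10 each). Of 12364 genes tested, 1957 were higher and 2199 lower in hypoxia CM by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, and the median change of these 4156 genes was 1.25-fold. A change of at least 2-fold was found for 33 of the higher and 173 of the lower genes. Scaled as log2(TPM + 1), the same libraries gave 769 higher and 2684 lower genes by limma, and log2(FPKM + 1) gave 906 and 2707. The share higher was 22.3% on the log2(TPM + 1) scale against 47.1% by the count test. No TMM factor was applied on these scales, where the median log2 fold change of all genes tested was -0.07 and -0.06. Gene and list values given below on these scales include that shift.

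**Figure D1:**
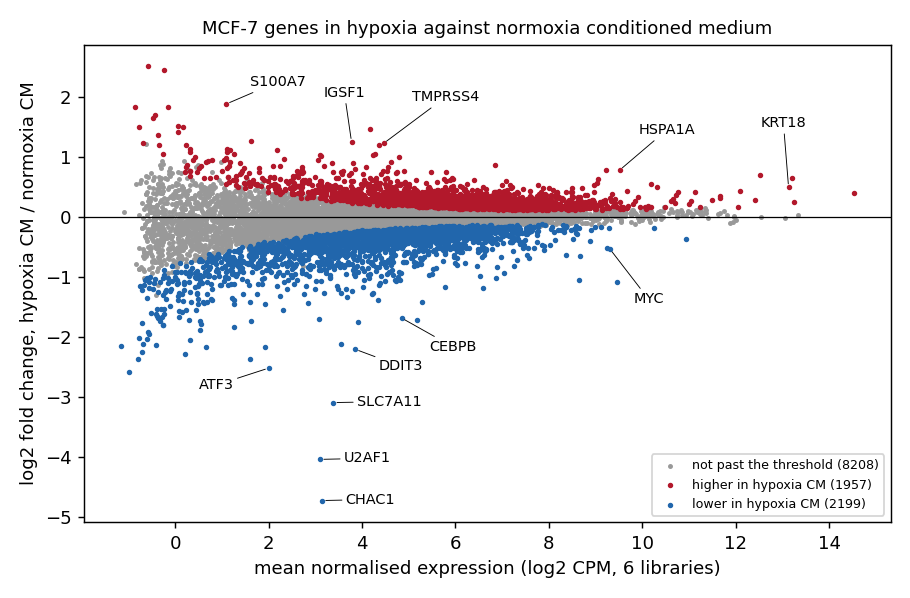
Each point is 1 of the 12364 genes tested, with its mean normalised expression over the 6 libraries (log2 CPM, x axis) and its log2 fold change in hypoxia CM against normoxia CM (y axis). Red points (1957) were higher and blue points (2199) lower at an adjusted p of 0.05 by edgeR, and the lowest named points are CHAC1 at -4.72, U2AF1 at -4.03, whose reads are shared with a near-identical copy, and SLC7A11 at -3.09.

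The genes with the largest falls were led by CHAC1 (gene ID 79094), which encodes an enzyme that degrades glutathione. Its log2 fold change was -4.72 ± 0.26 (SE, edgeR adjusted p = 1.1e-08), from counts of 223, 278 and 291 in the normoxia CM libraries and 3, 19 and 6 in the hypoxia CM libraries. SLC7A11 (gene ID 23657), the cystine importer, fell from 18.7 ± 0.643 to 2.19 ± 0.519 CPM (SD, n = 3), a log2 fold change of -3.09 ± 0.13. The stress-induced transcription factors ATF3 and DDIT3 (CHOP) changed by -2.51 ± 0.20 and -2.20 ± 0.12 (log2, SE). KCNJ14, a potassium channel gene, changed by -2.35, DMRTA1 by -2.28 and PRICKLE1, a planar cell polarity gene, by -2.16. DMRTA1 went from 1.92 ± 0.715 to 0.388 ± 0.0389 CPM and PRICKLE1 from 2.59 ± 0.720 to 0.572 ± 0.146 CPM (SD, n = 3). Counts in the hypoxia CM libraries were 6, 5 and 6 for DMRTA1 and 6, 10 and 9 for PRICKLE1. U2AF1, a splicing factor gene, had a log2 fold change of -4.03 but is uncertain, because its near-identical copy U2AF1L5 holds most of the reads of the pair. Both copies counted together differed by 0.03 ± 0.06 (log2, SE).

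Among the largest rises, S100A7 (psoriasin, gene ID 6278) went from 0.906 ± 0.183 to 3.36 ± 0.295 CPM (SD, n = 3), a log2 fold change of 1.88 ± 0.22 (SE, edgeR adjusted p = 1.8e-05). The complement protease gene C1R rose by 1.51, the metalloprotease gene ADAMTS7 by 1.42 and CLEC7A, which encodes the beta-glucan receptor dectin-1, by 1.26 (log2), all 3 from means under 2 CPM in normoxia CM. IGSF1 rose from 8.10 ± 0.274 to 19.3 ± 1.56 CPM, and TMPRSS4, a membrane serine protease gene, from 13.2 ± 0.618 to 30.9 ± 1.65 CPM. UGT1A6, a glucuronosyltransferase gene that shares exons with its neighbours and is therefore uncertain, rose from 12.5 ± 1.21 to 28.8 ± 1.55 CPM. RPL36A-HNRNPH2, a readthrough of a pair of genes whose reads it overlaps, had a log2 fold change of 1.47 and is uncertain for the same reason.

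In the list of ATF4 amino acid response genes, fixed before the data were examined, 19 of 28 tested members fell, 1 rose and 8 did not pass the test (1 and 20 when adjusted over the list alone). The median member was 1.40-fold lower and the camera adjusted p was 9.2e-11 (adjusted p = 0.088 with an estimated correlation). CEBPG and CEBPB, which encode transcription factors of the C/EBP family, fell from 75.3 ± 1.32 to 33.8 ± 1.06 CPM and from 43.8 ± 2.62 to 13.7 ± 1.43 CPM (SD, n = 3). The 3 enzymes of serine synthesis fell as well. PHGDH went from 220.5 ± 4.14 to 154.6 ± 5.25 CPM, PSAT1 from 36.2 ± 0.791 to 19.2 ± 0.931 CPM and PSPH from 28.4 ± 1.06 to 16.3 ± 0.162 CPM. They belong to the list of glutamine, serine and one-carbon metabolism, in which 3 of 18 members rose and 6 fell (camera adjusted p = 0.073, and 0.046 without hypoxia CM replicate 3). Without normoxia CM replicate 1, 5 rose and 7 fell, and on the log2(TPM + 1) scale 1 and 6. Once trends of fold change with abundance and transcript length were removed the list passed (camera adjusted p = 0.011), with 9 members lower. Several lists share members, SLC7A11, SESN2, ATF3 and TGFB2 among them, and so are not independent of one another.

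**Figure D2:**
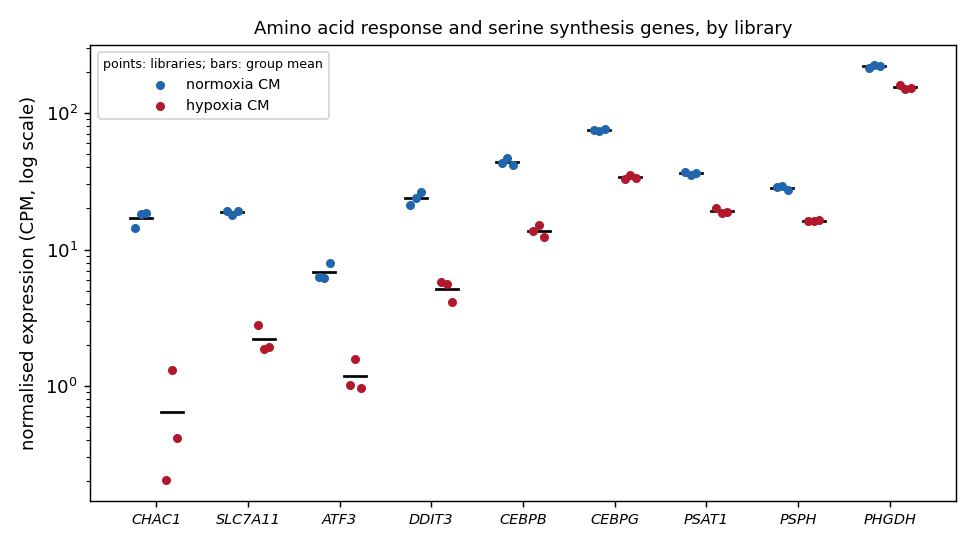
Normalised expression (CPM, log scale) of 9 genes of the amino acid response and of serine synthesis, with 1 point per library, blue for normoxia CM and red for hypoxia CM, and a bar at each group mean (n = 3). In each of these genes all 3 hypoxia CM libraries lie below all 3 normoxia CM libraries, as in CHAC1 with means of 17.1 and 0.641 CPM.

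Genes of DNA replication rose together, 27 of 36 tested members being higher and none lower (29 when adjusted over the list alone). The list's median was 1.18-fold, and it was the one list that passed camera both with the preset correlation (adjusted p = 4.3e-11) and with an estimated correlation (adjusted p = 0.040). On the log2(TPM + 1) scale 17 members were higher and 1 lower, with a median of 0.14. MCM2, a subunit of the replicative helicase, rose from 245.2 ± 2.25 to 328.8 ± 5.21 CPM (SD, n = 3). RRM2, of ribonucleotide reductase, rose by 0.46 ± 0.05 and PCNA, the polymerase clamp, by 0.48 ± 0.05 (log2, SE). In the mitosis list 9 of 37 members rose and 1 fell, the counts being the same adjusted over the list alone, with a median log2 fold change of 0.10 that was -0.00 on the log2(TPM + 1) scale (camera adjusted p = 0.021, or adjusted p = 0.34 with an estimated correlation). Without normoxia CM replicate 3 the counts were 3 higher and 2 lower, and on the log2(TPM + 1) scale 2 and 5. Removal of abundance and length trends ended the set call (camera adjusted p = 0.51), with 10 members higher and 5 lower. CCNB1 and PRC1 rose by 0.27 and 0.22, while CENPA, the centromeric histone variant, changed by -0.40. Replication-dependent histone genes went the other way, with 7 of 10 members lower and none higher (7 when adjusted over the list alone, camera adjusted p = 3.8e-04, adjusted p = 0.10 with an estimated correlation). H2AC6, H2BC5 and H2BC12 changed by -0.80, -0.63 and -0.51 (log2). Histone genes have near-identical relatives, and the sources used here do not say whether RNA was selected by poly(A), so their levels are uncertain.

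Glycolysis and lactate genes rose in 18 of 24 tested members and fell in none (19 when adjusted over the list alone), with a camera adjusted p of 6.1e-10 (adjusted p = 0.10 with an estimated correlation). By log2(TPM + 1) 13 were higher and 1 lower, with a median of 0.16 in place of 0.25, and with abundance and length trends removed 15 and 1. ALDOC, PFKP and ENO2 rose by 0.62 ± 0.06, 0.46 ± 0.04 and 0.57 ± 0.07 (log2, SE). LDHA, which converts pyruvate to lactate, rose from 532.3 ± 15.1 to 648.7 ± 6.53 CPM, and SLC2A1, the glucose transporter GLUT1, from 360.1 ± 14.9 to 455.1 ± 14.2 CPM (SD, n = 3). PDK1, an inhibitor of pyruvate dehydrogenase, rose by 0.32 ± 0.08 (log2, SE) by the count test, and limma on log2(TPM + 1) gave 0.16 with an adjusted p of 0.26. HK2 differed by 0.14 ± 0.05 (edgeR adjusted p = 0.051, and 0.020 without normoxia CM replicate 1). The lactate transporter genes SLC16A1 and SLC16A3 differed by -0.03 ± 0.09 and 0.14 ± 0.06 (edgeR adjusted p = 0.81 and 0.11), and SLC16A3 passed without normoxia CM replicate 3 (edgeR adjusted p = 0.039). Without abundance and length trends SLC16A1 stood at 0.05.

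Other metabolic lists rose by smaller amounts. Citric acid cycle genes were higher in 13 of 21 members (15 adjusted over the list alone), with a median of 1.11-fold (camera adjusted p = 3.6e-05, adjusted p = 0.088 with an estimated correlation), and SDHB, PDHA1 and IDH3G rose by 0.37, 0.29 and 0.27 (log2). The count fell to 6 without hypoxia CM replicate 1, to 7 without normoxia CM replicate 3 or hypoxia CM replicate 2, and to 4 on the log2(TPM + 1) scale, and to 8 with abundance and length trends removed. In the pentose phosphate list 6 of 9 members rose (6 adjusted over the list alone, camera adjusted p = 0.0053, adjusted p = 0.16 with an estimated correlation). G6PD, its first enzyme, rose from 696.2 ± 31.2 to 944.3 ± 29.7 CPM (SD, n = 3), and PRPS2 and TALDO1 by 0.50 and 0.31 (log2). On the log2(TPM + 1) scale 3 members of that list were higher and 1 lower, and with the trends removed 4 and 1. Nuclear-encoded respiratory chain genes rose in 13 of 44 members (13 adjusted over the list alone, camera adjusted p = 1.8e-04, adjusted p = 0.41 with an estimated correlation), COX6C by 0.42, UQCRC2 by 0.30 and ATP5MC3 by 0.30. The list's median of 0.09 turned to -0.01 on the log2(TPM + 1) scale, where the median of all genes was -0.07, with 5 members higher and 2 lower. Without hypoxia CM replicate 1 or hypoxia CM replicate 2, 8 were higher. Removal of abundance and length trends ended the set call (camera adjusted p = 0.43), with 9 members higher and 3 lower. Fatty acid oxidation genes were higher in 6 of 19 members, ACADVL by 0.54, PPARA by 0.42 and ETFDH by 0.29 (6 adjusted over the list alone, camera adjusted p = 0.015, adjusted p = 0.21 with an estimated correlation). PPARA did not pass on the log2(TPM + 1) scale (limma adjusted p = 0.16), nor did ETFDH (limma adjusted p = 0.067). Of that list 3 members were higher without hypoxia CM replicate 2 and 1 on the log2(TPM + 1) scale, where the set call ended (camera adjusted p = 0.057), as it did with the trends removed (camera adjusted p = 0.0998).

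In the fatty acid synthesis list 9 of 19 members rose and 3 fell (9 and 4 adjusted over the list alone, camera adjusted p = 0.020, adjusted p = 0.16 with an estimated correlation). FASN, the fatty acid synthase, rose from 1490 ± 39.5 to 1995 ± 22.1 CPM and ELOVL1 by 0.34 (log2), whereas DGAT2, which makes triglycerides, changed by -0.52. Without normoxia CM replicate 3, 5 members were higher, and on the log2(TPM + 1) scale 4 were higher and 4 lower. Cholesterol synthesis genes were higher in 7 of 23 members (8 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.010, adjusted p = 0.10 with an estimated correlation), DHCR24 by 0.44, MVD by 0.35 and LSS by 0.28. LSS had a limma adjusted p of 0.063 on the log2(TPM + 1) scale, where 4 members of the list were higher and 1 lower. Lysosome and autophagy genes rose in 11 of 26 members (13 adjusted over the list alone, camera adjusted p = 1.6e-04, adjusted p = 0.10 with an estimated correlation), with GLA, CTSD and CTSB at 0.65, 0.38 and 0.31, and on the log2(TPM + 1) scale 5 were higher and 2 lower.

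Heat shock genes rose in 13 of 15 members (13 adjusted over the list alone), with a camera adjusted p of 1.3e-08 (adjusted p = 0.10 with an estimated correlation). HSPA1A and HSPA1B, near-identical copies that encode the inducible chaperone HSP70 and whose division of reads is uncertain, rose by 0.78 ± 0.05 and 0.64 ± 0.05 (log2, SE), and HSPA8 by 0.50 ± 0.05. Once abundance and length trends were removed, 9 heat shock members were higher (8 on the log2(FPKM + 1) scale) and the list's median went from 0.27 to 0.15. Chaperones of the endoplasmic reticulum and other genes of the unfolded protein response went both ways, 8 of 22 being higher and 3 lower, also when adjusted over the list alone, with a median of 0.07 that was -0.01 on the log2(TPM + 1) scale (camera adjusted p = 0.090, and 0.042 without normoxia CM replicate 1). HSPA5 (BiP) and XBP1 rose by 0.29 each, and HERPUD1 changed by -0.60. Without hypoxia CM replicate 1 or hypoxia CM replicate 2, 5 of that list were higher and 2 lower, and on the log2(TPM + 1) scale 3 and 2. Of 19 genes of the NRF2 response to oxidative stress 7 rose, NQO1 by 0.42 among them, and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.030, adjusted p = 0.16 with an estimated correlation). That call ended without normoxia CM replicate 1 (camera adjusted p = 0.056) or hypoxia CM replicate 2 (camera adjusted p = 0.053), and with abundance and length trends removed (camera adjusted p = 0.0998). The members higher numbered 4 by DESeq2 or without normoxia CM replicate 3, hypoxia CM replicate 1 or hypoxia CM replicate 2, and 2 on the log2(TPM + 1) scale. Because SLC7A11 is a member, the list's mean was -0.00 while its median was 0.17.

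Among genes named for hypoxia itself, HIF1A rose from 69.6 ± 5.64 to 86.6 ± 2.80 CPM and VEGFA fell from 94.4 ± 3.44 to 74.3 ± 0.301 CPM (SD, n = 3). CA9 had 1.79 ± 0.253 CPM in normoxia CM and 1.12 ± 0.377 CPM in hypoxia CM (edgeR adjusted p = 0.069, limma adjusted p = 0.022 on the log2(TPM + 1) scale). HIF target genes outside glycolysis went both ways, with 12 of 31 members higher and 7 lower (14 and 8 adjusted over the list alone), a median of 0.09, a mean of -0.02 and a camera adjusted p of 0.25. On the log2(TPM + 1) scale 6 were higher and 7 lower. CA12 rose by 0.36, whereas STC2 and DDIT4 changed by -1.02 and -0.52 (log2).

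Of 5 lists of signalling targets and early response genes, 4 passed camera downwards and the Notch and Wnt list did not, though it passed by fry (adjusted p = 0.0014). In the YAP and TAZ list 10 of 15 members were lower and none higher (10 adjusted over the list alone, camera adjusted p = 1.2e-04, adjusted p = 0.10 with an estimated correlation), AMOTL2 by -0.97, CCN1 by -0.94 and TGFB2 by -1.70 (log2). TGF-beta response genes were lower in 11 of 17 members and higher in 1 (14 and 2 adjusted over the list alone, camera adjusted p = 2.3e-05, adjusted p = 0.10 with an estimated correlation), with SMAD6 going from 36.5 ± 2.37 to 18.2 ± 1.68 CPM and TGIF1 at -0.80. Both of these encode repressors of signalling by the TGF-beta family. TGFB2 belongs to this list as well as to the YAP and TAZ list. Of 23 immediate early genes, induced within minutes by growth factors or stress, 10 fell and 3 rose (13 and 3 adjusted over the list alone, camera adjusted p = 0.0011, adjusted p = 0.21 with an estimated correlation). Their median went from -0.33 to -0.20 with abundance and length trends removed. JUN fell from 59.6 ± 4.88 to 30.8 ± 1.56 CPM and MYC from 747.9 ± 32.3 to 517.9 ± 3.11 CPM (SD, n = 3). The p53 list had 12 of 27 members lower and none higher (12 adjusted over the list alone, camera adjusted p = 0.0019, adjusted p = 0.10 with an estimated correlation), with SESN2, also an ATF4 target, at -0.96, BTG2 at -0.61 and CDKN1A (p21) at -0.38. With abundance and length trends removed 1 p53 member was higher and the median went from -0.18 to -0.10. Notch and Wnt targets were lower in 6 of 17 members and higher in 2, also when adjusted over the list alone (camera adjusted p = 0.11), RNF43 by -0.77 and DKK1 by -0.52, while NOTCH3 rose by 0.32.

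**Figure D3:**
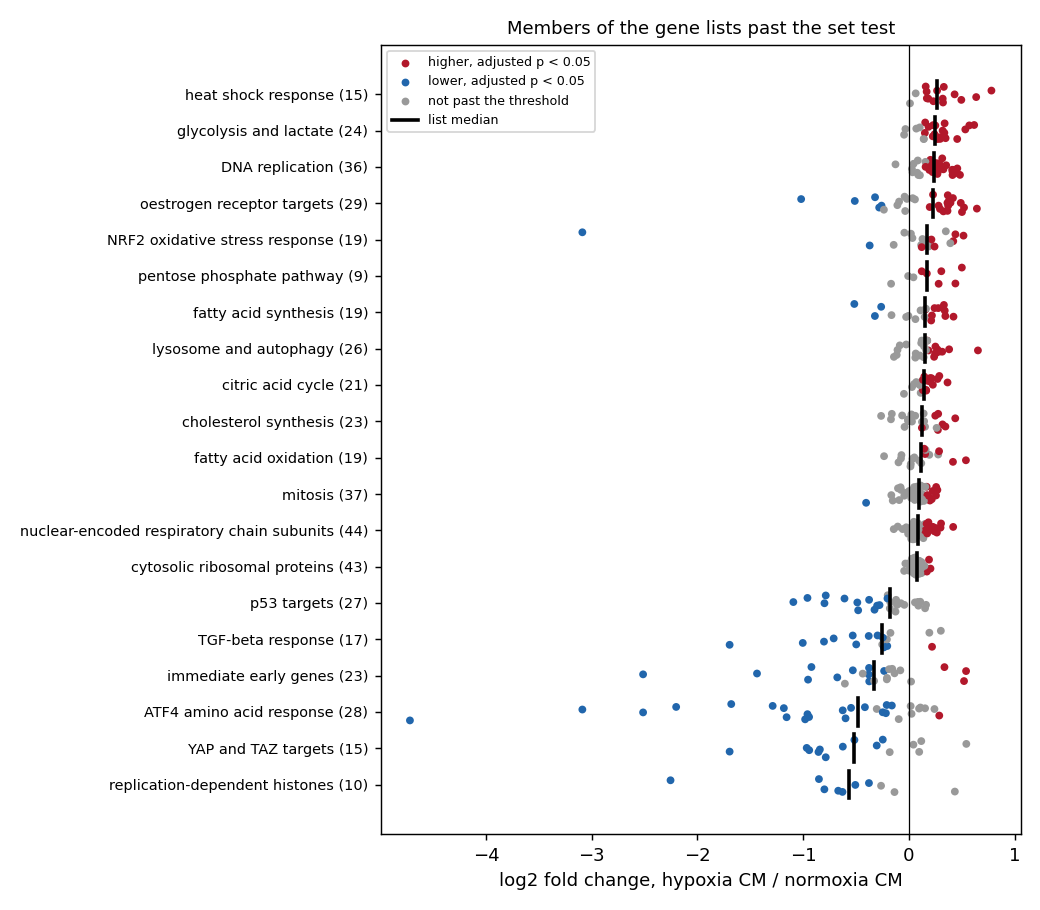
Log2 fold changes (hypoxia CM against normoxia CM, x axis) of the tested members of the 20 gene lists past the set test at the preset correlation, of which 1 passed with an estimated one, with the number of tested members after each name. Points are genes, coloured red where higher and blue where lower at an adjusted p of 0.05 by edgeR, and black bars are list medians, from -0.57 for histones to 0.27 for heat shock genes. On the log2(TPM + 1) scale the medians of respiratory chain, mitosis and ribosomal protein genes were -0.01, -0.00 and -0.02. The median of all genes on that scale was -0.07.

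Oestrogen receptor targets rose in 16 of 29 members and fell in 5 (16 and 6 adjusted over the list alone, camera adjusted p = 0.0065, adjusted p = 0.10 with an estimated correlation). On the log2(TPM + 1) scale 11 were higher and 6 lower. CCND1 (cyclin D1) rose from 430.9 ± 17.4 to 575.1 ± 17.9 CPM (SD, n = 3) and CA12 by 0.36 (log2), whereas STC2 changed by -1.02. ESR1, which encodes the receptor, rose by 0.17 ± 0.05 (edgeR adjusted p = 0.024), a call that ended without normoxia CM replicate 2, normoxia CM replicate 3 or hypoxia CM replicate 3 (edgeR adjusted p = 0.081, 0.089 and 0.10). Luminal epithelial genes went both ways, 10 of 20 being higher and 6 lower (11 and 6 adjusted over the list alone, camera adjusted p = 0.073, and 0.038 without normoxia CM replicate 2). Without normoxia CM replicate 3, 7 were higher and 3 lower, and without hypoxia CM replicate 1, 8 and 2. In log2(TPM + 1) values 5 were higher and 6 lower, and once abundance and length trends were removed 8 and 7, with a median that went from 0.13 to 0.03. The list passed with no filter on low counts (camera adjusted p = 0.039). KRT18, a luminal keratin, rose from 7465 ± 580.1 to 10511 ± 240.4 CPM and ELF3 by 0.53 (log2), whereas FOXA1, a pioneer factor for the oestrogen receptor, fell from 493.2 ± 20.2 to 315.1 ± 6.38 CPM.

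Of 14 breast cancer stem cell markers 6 fell and none rose (6 adjusted over the list alone), with a camera adjusted p of 0.062, or 0.036 without normoxia CM replicate 2 and 0.047 without hypoxia CM replicate 3. BMI1 and NOTCH1 changed by -0.67 and -0.35 (log2). SOX2, with 0.862 ± 0.0760 CPM in normoxia CM and 0.366 ± 0.0812 CPM in hypoxia CM (edgeR adjusted p = 0.017), lost its call without normoxia CM replicate 2, normoxia CM replicate 3 or hypoxia CM replicate 1 (edgeR adjusted p = 0.051, 0.052 and 0.082). CD44 and ALDH1A3 differed by 0.04 ± 0.08 and 0.23 ± 0.20 (log2, SE, edgeR adjusted p = 0.69 and 0.42), and CD44 stood at -0.02 without normoxia CM replicate 2. In the epithelial to mesenchymal list 1 of 11 members rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.72), and 3 rose and 2 fell with abundance and length trends removed. S100A4 rose by 0.72, while VIM and FN1 changed by -0.92 and -0.33.

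Among immune genes, CD274 (PD-L1) had 0.973 ± 0.402 CPM in normoxia CM and 1.74 ± 0.558 CPM in hypoxia CM (SD, n = 3), a log2 difference of 0.84 ± 0.33 (SE, edgeR adjusted p = 0.060). It passed without normoxia CM replicate 2 or hypoxia CM replicate 2 (edgeR adjusted p = 0.028 and 0.020), and its counts were 15, 21 and 9 against 29, 16 and 31. Immune checkpoint and ligand genes went both ways, 3 of 19 being higher and 5 lower (6 and 6 adjusted over the list alone), with a median of 0.08, a mean of -0.08 and a camera adjusted p of 0.92. Single libraries moved those counts, to 5 and 5 without normoxia CM replicate 2, 2 and 2 without normoxia CM replicate 3 or hypoxia CM replicate 1, 3 and 2 without hypoxia CM replicate 2, and 3 and 3 without hypoxia CM replicate 3. Removal of the trends gave 6 and 3, DESeq2 2 and 3, and the replicate block 6 and 5. ULBP1, a ligand of the activating receptor NKG2D, fell from 6.16 ± 0.950 to 1.37 ± 0.127 CPM, VTCN1 (B7-H4) changed by -0.62, and MICA rose by 0.31. CD47 changed by -0.18 (edgeR adjusted p = 0.022), but leaving out normoxia CM replicate 1, normoxia CM replicate 3 or any hypoxia CM replicate ended that call (edgeR adjusted p = 0.055, 0.085, 0.076, 0.051 and 0.065). Antigen presentation genes were higher in 3 of 17 members, also when adjusted over the list alone, with a median of 0.05 that was -0.03 on the log2(TPM + 1) scale, where 1 was higher and 1 lower (camera adjusted p = 0.35). HLA-C rose by 0.31 and HLA-A by 0.22 (edgeR adjusted p = 0.013, and 0.091 without hypoxia CM replicate 1), both uncertain because HLA genes share reads, and B2M differed by 0.06 ± 0.05, or -0.03 on the log2(TPM + 1) scale. Interferon-stimulated genes were higher in 1 of 22 members and lower in 4 (0 and 4 adjusted over the list alone, camera adjusted p = 0.46), USP18 by -0.50 and IRF7 by -0.48. Without normoxia CM replicate 2 or with the trends removed, 2 were higher, and leaving out any other single library gave 0 higher. In the NF-kB, cytokine and chemokine list 2 of 20 members rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.35), against 0 and 5 on the log2(TPM + 1) scale and 4 and 4 with the trends removed, with CCL2 at -1.44, NFKB1 at -0.30 and CXCL12 at 0.23.

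Cytosolic ribosomal protein genes were higher in 4 of 43 members (3 adjusted over the list alone), with a median of 0.08 that was -0.02 on the log2(TPM + 1) scale and -0.07 once abundance and length trends were removed (camera adjusted p = 0.0019, adjusted p = 0.54 with an estimated correlation). Without normoxia CM replicate 2, 14 members were higher, without normoxia CM replicate 3 or hypoxia CM replicate 1, 2 were, and with the trends removed 0 were higher and 11 lower. Ribosome biogenesis genes went both ways, 7 of 28 being higher and 4 lower (7 and 5 adjusted over the list alone), with a median of 0.01, a mean of -0.01 and a camera adjusted p of 0.74. The counts were 2 higher and 8 lower on the log2(TPM + 1) scale, and 5 and 8 with the trends removed. ODC1, NOP2 and RRP12 changed by -0.44, -0.41 and -0.32. Metallothionein and zinc transport genes were higher in 2 of 6 members and lower in 1, also when adjusted over the list alone (camera adjusted p = 0.68, upwards, with a median of -0.02 and a mean of -0.00), and lower in 2 on the log2(TPM + 1) scale or with the trends removed, SLC30A1 at -0.53 and SLC39A6 at 0.27. Markers of other cell types were few. In the fibroblast and endothelial lists none of 3 tested members passed, the most abundant fibroblast marker being COL1A1 at 22.4 ± 2.27 and 19.1 ± 1.62 CPM and the most abundant endothelial marker EMCN at 4.16 ± 0.193 and 3.38 ± 0.467 CPM (normoxia CM and hypoxia CM, SD, n = 3). Of 3 leukocyte markers CD68 rose by 0.72, and of 7 basal and myoepithelial markers 1 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.78, upwards, with a median of -0.07 and a mean of 0.03), against 1 and 0 with the trends removed. The basal marker TP63 lost its call without hypoxia CM replicate 3 (edgeR adjusted p = 0.066). ACTA2, the one that fell, at -0.51, lost its call without normoxia CM replicate 2, normoxia CM replicate 3, hypoxia CM replicate 1 or hypoxia CM replicate 3 (edgeR adjusted p = 0.074, 0.15, 0.10 and 0.12). In the fibroblast list 1 member was lower without normoxia CM replicate 1 or hypoxia CM replicate 2, and in the leukocyte list 1 without hypoxia CM replicate 3.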

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

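The trend correction and the counts without MTRNR2L genes were chosen after the data were seen, and the other settings before. The number of genes past the threshold lay between 2996 (without hypoxia CM replicate 1) and 4234 (without normoxia CM replicate 1) when single libraries were left out, and every call shared with the full set of libraries kept its direction under each setting. DESeq2 gave 1581 higher and 1604 lower genes, upper quartile scaling 1686 and 2410, and the trend correction 2261 and 2170, with 3521 of the 4156 calls shared. RLE gave 2023 and 2165, no filter 1957 and 2099, a mean of at least 1 CPM 1923 and 2180, voom 1946 and 2197, and counts without the MTRNR2L genes 1952 and 2197, with 4148 calls shared. A 2-fold minimum left 206 genes, 33 higher and 173 lower, because it removes small changes by construction. On the log2(TPM + 1) and log2(FPKM + 1) scales 769 and 906 genes were higher, and the cause was not tested. The median gene shifted by -0.07 and -0.06 on these scales, to which no TMM factor was applied. Those factors were 1.03, 1.01 and 1.04 in normoxia CM and 0.971, 0.970 and 0.983 in hypoxia CM. List medians and member counts on these scales include that shift of the median gene. With an estimated correlation 1 list passed camera in place of 20, and fry called 24. The estimate was above the preset 0.01 for some lists that lost the call, such as glycolysis (0.12). For others it was below, such as the citric acid cycle (-0.0034), p53 targets (-0.0083) and cholesterol synthesis (-0.025). A higher correlation therefore cannot account for the loss in these latter lists. Fry called some lists that camera with the preset correlation did not. They were Notch and Wnt targets, glutamine, serine and one-carbon genes and stem cell markers (fry adjusted p = 0.0014, 0.0013 and 0.0022). Luminal, endoplasmic reticulum and interferon-stimulated genes were also called (fry adjusted p = 0.012, 0.044 and 0.047). Fry did not call the respiratory chain or ribosomal proteins (fry adjusted p = 0.070 and 0.26). With the replicate number as a block 4138 genes passed, 1919 higher and 2219 lower, with 119 named genes and 21 lists. Same-numbered libraries had deviation correlations of -0.06, 0.08 and -0.08, which gave no sign of pairing by number. No library correlated best with the same-numbered library of the other group.

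Over all settings, named genes kept direction and side of the threshold in 2059 comparisons, lost the call in 52 and gained it in 10, and lists in 516, 33 and 14. Some directions reversed, and the cause was not tested. SLC16A1 stood at 0.0472 with the trend correction, the gene B2M at -0.0268 and -0.0172 on the TPM and FPKM scales, and CD44 between -0.0205 and 0.120 without single libraries. Camera takes its direction from the mean statistic of the members against that of the other genes, which can differ from the sign of the median. List medians in this paragraph come from the fits that camera used (voom for counts). They can therefore differ from the edgeR medians given above. With the trend correction this direction changed for ribosomal proteins (median 0.08 to -0.0731, adjusted p = 0.0059), and for lists that passed in neither fit, ribosome biogenesis (0.01 to -0.0505), the epithelial to mesenchymal list (-0.15 to 0.0121) and metallothioneins (-0.02 to 0.0331). On the TPM scale it changed for ribosome biogenesis (-0.0810), and also for the epithelial to mesenchymal list (-0.0828) and metallothioneins (-0.119), whose medians kept their sign. On the FPKM scale it changed for ribosome biogenesis (-0.0712), and for NF-kB targets (-0.0125), whose median kept its sign. The trend correction ended the set calls of fatty acid oxidation (median 0.12 to 0.06, adjusted p = 0.0998), mitosis (0.10 to 0.04), NRF2 genes and the respiratory chain (0.09 to 0.02), and brought the medians of pentose phosphate (0.17 to 0.06), cholesterol synthesis (0.12 to 0.06), heat shock (0.27 to 0.15), glycolysis (0.25 to 0.16), p53 (-0.20 to -0.10) and immediate early genes (-0.32 to -0.20) nearer to 0, though their set calls passed. It gave a call to glutamine, serine and one-carbon genes (-0.10 to -0.13, adjusted p = 0.011). By fry directions changed for ribosome biogenesis (0.0106) and immune checkpoint genes (0.0765), whose median lay between 0.0511 and 0.143 without single libraries. Quantile normalization, another pseudocount and limma without trend were planned only for a table without counts and were not run, and no set test used DESeq2 fits. By DESeq2 4 NRF2 members were higher and 1 lower, and 2 and 3 immune checkpoint members. Depth limits genes near 1 CPM, such as CD274 and SOX2, which have 4 to 31 counts per library.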

Other observations

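The genes in this paragraph and the next were chosen after their values were seen. TXNIP, which encodes an inhibitor of thioredoxin and of glucose uptake, fell from 952.6 ± 18.9 to 451.9 ± 6.96 CPM (SD, n = 3), and its relatives ARRDC4 and ARRDC3 from 55.7 ± 3.15 to 16.9 ± 0.431 CPM and from 23.3 ± 2.02 to 6.91 ± 0.979 CPM. ARRDC4 and TXNIP had the smallest p of all genes tested (edgeR adjusted p = 8.8e-10 each). MAT2A, which makes S-adenosylmethionine, fell from 542.5 ± 20.9 to 261.9 ± 10.6 CPM. ADM2 and JDP2 changed by -2.12 ± 0.12 and -1.41 ± 0.08 (log2, SE), ALDH1L2, of mitochondrial one-carbon metabolism, by -2.13 ± 0.39, and CARS1, the cysteinyl-tRNA synthetase, by -0.85 ± 0.06.

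KRT8 and KRT19, keratin genes of the luminal list that went both ways, rose from 20395 ± 1633 to 26970 ± 254.5 CPM and from 3737 ± 212.4 to 5029 ± 279.2 CPM (SD, n = 3, edgeR adjusted p = 2.7e-04 and 7.4e-05). SUSD3, TMPRSS2, SAT1, which encodes an enzyme that acetylates polyamines, and DRAM1, of the lysosomal membrane, rose by 0.87 ± 0.06, 0.84 ± 0.08, 0.91 ± 0.09 and 0.91 ± 0.07 (log2, SE).

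All tests in the following paragraphs were chosen after the results were seen, except the count over other splits of the libraries. That count was 1 of 10 splits of the 6 libraries into 3 and 3 with as many genes, the real one with 4156. The highest of the other splits had 0 by edgeR at the adjusted threshold and 654 at an unadjusted p under 0.05, against 5344 for the real split. With 10 splits no share under 0.05 can be reached. Every other split also holds libraries of both groups on each side. A difference between the groups then widens the spread, so low counts in those splits follow from it and are no separate evidence.

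The fall of the ATF4 list was weighed against 2 explanations. A trend of fold change with abundance was present across genes (rho = 0.24 with log2 CPM and -0.10 with effective length, genes not being independent), but 20 members were lower after the trend was removed, against 19 before. Deviations of single libraries from the gene means had a rho with length from -0.23 (hypoxia CM replicate 2) to 0.34 (normoxia CM replicate 1). Both signs occurred within each group. A lower load of misfolded protein in the endoplasmic reticulum would lower the chaperones of that compartment. The list of these chaperones and other unfolded protein response genes had a median of 0.0668 (bootstrap interval over genes -0.005 to 0.166). It showed no general fall, with 8 of 22 members higher and 3 lower. Because the list is mixed and the bootstrap took genes as independent, this does not exclude that explanation. A response to amino acid supply, which may differ between the media because hypoxic cells consume nutrients differently, also stays open. No medium was measured. An ATF4 response is known to act on cytosolic and not mitochondrial aminoacyl-tRNA synthetase genes. Of 20 cytosolic genes 8 were lower and 4 higher, against 1 and 5 of 17 mitochondrial ones (difference of medians -0.12, one-sided permutation test over genes, p = 0.032), but the 14 cytosolic genes outside the ATF4 list differed by -0.0369 (p = 0.36), so this test does not bear the hypothesis beyond the list's own members.

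The rises of 3 metabolic lists, glycolysis, citric acid cycle and respiratory chain, were weighed against the same trend, since genes in the lowest eighth by abundance had a median log2 fold change of -0.18 and those in the highest 0.08. After its removal 15 glycolysis members were higher and 1 lower, against 18 and 0 before, and the list's median went from 0.25 to 0.16 (camera adjusted p = 1.2e-05), which argues against the trend as the whole cause. For the citric acid cycle 8 members and for the respiratory chain 9 were higher (with 3 respiratory chain members lower), against 13 before in each, between the bounds set for either outcome, so trend and condition cannot be told apart for these lists. Their set tests, read beside those counts, moved apart. The citric acid cycle median went from 0.15 to 0.10 (SD of members 0.0929, camera adjusted p = 0.0074). The respiratory chain median went from 0.09 to 0.02 (SD of members 0.111, camera adjusted p = 0.43), and its call ended. The trend itself may be technical or part of the response, and its removal would take away either.

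Reads of near-identical copies were weighed for 2 changes. U2AF1 counts were 460, 202 and 90 in normoxia CM and 25, 0 and 18 in hypoxia CM, but with U2AF1L5 added the log2 fold change was 0.0286 ± 0.055 (SE), which fits a different division of reads between the copies. All 6 tested MTRNR2L genes, nuclear copies of part of the mitochondrial 16S ribosomal RNA gene at unlinked loci, were higher, by 0.64 to 0.99 (log2), and their share of counts went from 1.27% ± 0.105 to 1.92% ± 0.108 (SD, n = 3). These genes were picked because they were higher, so the count of 6 decides nothing about reads of the mitochondrial RNA assigned to the copies. That explanation and a change between the media both stay open.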
